A study of Homo sapiens with 3 samples.

How the data were processed

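Total RNA of HepG2 cells given 20 µM A740003, 20 µM A438079 or PBS for 48 h was made into mRNA-seq libraries with a SMARTer kit after RNeasy extraction, per the labels' protocols. There was 1 library per treatment, and the 3 value columns were matched to the samples by the letter that each sample's label gives.

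The authors deposited a table of expected counts per gene and a table of FPKM values per gene, each with 62680 rows, nearly all with a human Ensembl gene identifier. The deposited expected counts are estimates that need not be whole, with 35.1%, 34.8% and 33.3% of the values above 0 not whole in the A740003, A438079 and PBS libraries. The deposited FPKM values are scaled for gene length and library size as the authors computed them. The submitters' processing notes name the build GRCm38, a mouse assembly, although the rows are human genes, so the build used for the counts is unclear. The aligner, counting tool and annotation are not given in the sources used here, nor is the use of strand, so antisense and overlapping genes are uncertain. Of the rows, 116 carry no Ensembl identifier, hold 0.0791%, 0.0775% and 0.0853% of counts, and stayed in the library totals.

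Expected counts were rounded to whole numbers. The design was fixed for raw counts before the data were examined, and the same steps were applied to the rounded values. Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.01, 0.989 and 1.00 for A740003, A438079 and PBS. The 12270 genes with a mean of at least 1 CPM over the 3 libraries were compared. A CPM of 1 was 19.4 to 19.9 counts, and the median gene had 439 counts, so precision was set by counting for low genes. With 1 library per treatment no p-value was computed. A gene was called higher or lower when the ratio of scaled counts was at least 2 (or at most the inverse) and the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio excluded 1. Log2 ratios used a pseudocount of 0.5 counts. The intervals cover counting error only.

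Named genes followed a rule fixed before the data were examined. It took P2RX7 and P2RX4, the 10 highest and 10 lowest genes of each comparison, ranked by the interval bound nearest to 1, among genes with a symbol, a mean of at least 5 CPM and a ratio of at least 2, and the 10 highest and 10 lowest in both antagonist libraries. It also took up to 4 members of each fixed list with at least 5 CPM and the largest ratios over PBS. Further members of the lists (DHCR7, FDFT1, IDI1, HMGCS1, PMVK, LGR5, DKK1, PEG3, FGB, MT-ND4L, MT1F, MT2A and ESAM) and the partner genes in summed loci were named after their values were seen. Results for 3 members of the cholesterol list taken singly are not reported here.

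For each of 41 gene lists fixed before the data were examined, members with at least 1 CPM were counted as at least 1.5-fold higher or lower with an interval that excluded 1. The list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with 1 measured gene were not placed. Correlation and overlap between the antagonists were set beside 100 simulations of unchanged libraries against the same PBS library.

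Transcript GC content and length were taken from GENCODE release 29 (GRCh38) by gene identifier, for 11906 of the 12270 genes (97.0%). A step added after the data were seen subtracted from each log2 ratio the median of the 201 genes nearest in rank of GC content and length. Genes were also marked as whole when their expected counts were within 0.005 of a whole number in all 3 libraries, which held for 6233 genes (50.8%). Reads of the other genes may be split with paralogs, pseudogenes or overlapping genes. Counts were summed for some such loci: SULT1A3 with SULT1A4, BLOC1S5-TXNDC5 with TXNDC5, FAM156A with FAM156B, RPS28 with RPS28P7, and the UGT1A family. They were not summed for others, such as RPL36A-HNRNPH2, ZNF625-ZNF20, BZW1P2 or C4A and C4B.

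The steps were tested on simulated data. For A740003 over PBS, with 12270 genes and an assumed coefficient of variation of 0.1, the size rule found 3 of 50 genes changed 1.5-fold, 22 of 50 changed 2-fold, 46 of 50 changed 3-fold and 50 of 50 changed 4-fold, and called 0.472% of unchanged genes. For A438079 over PBS, 9 of 200 unchanged lists of 24 genes lay outside the central 95% of random lists, and a list of 24 shifted by -0.5 kept a median of -0.53 after an added GC and length trend was removed. Genes varied independently in these simulations, so they do not cover lists whose members vary together.

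Alternatives were total counts, DESeq2 1.42.0 size factors, upper quartile scaling, other filters, fold sizes and interval rules, the authors' FPKM values with pseudocounts of 0.1 and 1, protein-coding genes, and random lists matched also on length. Alternatives added after the data were seen were the GC and length step, random lists matched also on GC content, whole genes alone, and counts that were not rounded. Genes with an identifier alone were not named. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.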

Results

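RNA-seq was carried out on HepG2 cells, a human line derived from a liver carcinoma, after 48 h with 20 µM A740003, 20 µM A438079 or PBS. The labels describe both compounds as antagonists specific for P2X7, an ATP-gated ion channel encoded by P2RX7, and name PBS as the control. The solvent of the compounds is not given in the sources used here, so a solvent effect shared by both antagonist libraries cannot be separated from the compounds. Each treatment was 1 library, so no difference has a replicate check, no test of the treatments was possible, and every interval covers counting error between libraries only. Expected counts summed to 19735540 in the A740003 library, 19606723 in the A438079 library and 19375462 in the PBS library. The 12270 genes with a mean of at least 1 CPM (counts scaled for library size), were compared as ratios of scaled counts.

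P2RX7 (ENSG00000089041; chromosome 12, 121132819 to 121188032, plus strand, GENCODE release 29 on GRCh38), the gene of the channel both compounds are directed at, had 2 counts in each of the 3 libraries. The exact Poisson 95% intervals were 0.0122 to 0.363 CPM with A740003, 0.0125 to 0.373 with A438079 and 0.0125 to 0.372 with PBS. A difference in P2RX7 between treatments was not detectable at this depth. P2RX4 (ENSG00000135124; chromosome 12, 121209857 to 121234106, plus strand, same annotation), which encodes a related ATP-gated channel, had 219, 247 and 249 counts in the A740003, A438079 and PBS libraries. Its ratio over PBS was 0.858 (95% counting interval 0.712 to 1.03) with A740003 and 0.994 (0.830 to 1.19) with A438079, and both intervals include 1. Of 32 genes for purinergic receptors, ATP release and ATP-degrading enzymes, 16 were measured. None was at least 1.5-fold higher and 2 were at least 1.5-fold lower in each antagonist library. ADORA2A, an adenosine receptor gene, stood at 0.871 times PBS (0.694 to 1.09) with A740003 and 0.596 times (0.461 to 0.768) with A438079, and at log2 ratios of 0.19 and -0.41 with the trend in transcript GC content and length removed. ENPP3 and ENTPD1, which encode ectoenzymes that cleave nucleotides, stood at 1.31 and 1.20 times PBS with A740003 and at 1.20 and 1.27 times with A438079. The list's median log2 ratio was -0.15 with A740003 (percentile 11.95 among 10000 random lists matched on expression) and -0.27 with A438079 (percentile 1.23). The A438079 value was inside the central 95% of random lists at a mean of at least 5 CPM (median -0.002, percentile 50.1), with FPKM (percentile 31.5), with whole counts only (percentile 13.7) and with that trend removed (percentile 8.08). Such percentiles describe these libraries and do not test the treatments.

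The first comparison asked how cells given A740003 differed from cells given PBS. The gene of the fatty acid synthase, FASN, was the lowest by the naming rule, at 0.126 times the PBS level (95% counting interval 0.103 to 0.153; 120 against 928 counts). IGF2, a fetal growth factor gene with fractional expected counts, stood at 0.170 times (0.159 to 0.182). UGT1A1, whose product conjugates bilirubin, was higher, with 1459 against 648 counts. The 13 mRNAs of the mitochondrial genome had a median log2 ratio of -0.33, with 12 of 13 below PBS, and the metallothionein and zinc transport list had a median of 0.34. Among all genes compared, 141 were at least 2-fold higher and 670 at least 2-fold lower in the A740003 library. At a mean of at least 5 CPM, which 9589 of the 12270 genes reached, 16 were higher and 279 lower. Over all genes, unchanged libraries simulated at an assumed coefficient of variation of 0.2 gave 177 higher and 175 lower genes in this comparison. At 0.1 they gave 21.4 and 19.7.

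PRRC2A, SBF1, MMP15, HCFC1 and PELP1 stood at 0.148, 0.154, 0.163, 0.163 and 0.180 times PBS. SCRIB, a cell polarity gene, stood at 0.126 times (0.080 to 0.189) and PIEZO1, a mechanically gated channel gene, at 0.147 times (0.097 to 0.217). BZW1P2, a pseudogene, stood at 0.170 times and may share reads with its parent gene. The GC and length values of the lower genes differed from those of the rest. Their median transcript GC content was 60.7% and their median transcript length 4166 nt, against 47.8% and 3260 nt over all genes compared. Of the 652 lower genes with both values, 77.1% had a GC content of at least 55.9%, a value that 25% of all genes reach. When the trend with GC content and length was removed, a step added after the data were seen, 125 genes were at least 2-fold higher and 284 lower, so that lower genes made up 69.4% of those past the threshold instead of 82.6%. That step moved the log2 ratio of FASN from -2.98 to -1.60, of IGF2 from -2.55 to -1.63, of PRRC2A from -2.75 to -1.46, of SCRIB from -2.97 to -1.81, of SBF1 from -2.69 to -1.35, of MMP15 from -2.60 to -1.49, of HCFC1 from -2.60 to -1.30, of PIEZO1 from -2.75 to -1.36 and of PELP1 from -2.47 to -2.06.

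All 10 of the highest genes had fractional expected counts in at least 1 library, so that reads shared with other genes make each of them uncertain. POLR2L, a subunit gene common to the nuclear RNA polymerases, stood at 2.05 times PBS (1.81 to 2.33). TMEM256 stood at 2.35 times, RN7SL1, a signal recognition particle RNA, at 3.53 times, and RPL36A-HNRNPH2, a readthrough of neighbouring genes, at 2.54 times. CMC4 stood at 2.40 times with A740003 and at 0.987 times with A438079. The ribosomal protein pseudogene RPS28P7 stood at 2.81 times PBS, and its counts summed with those of RPS28 at 1.92 times (1.81 to 2.05). UGT1A1 and UGT1A3 share their last exons with the other UGT1A genes. The 9 annotated UGT1A rows summed to 2729 counts with A740003 against 1365 with PBS, a ratio of 1.95 (1.83 to 2.08).

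Of the 39 lists with enough measured genes, 8 had a median below the central 95% of random lists in the A740003 library over PBS. A median above it was seen for 1 list. If genes varied independently, 1.95 lists would lie outside. Members of a list can vary together, so more may lie outside by chance. With the GC and length trend removed, 4 lay below and 1 above. The 13 mitochondrial mRNAs lay below all 10000 random lists. MT-ND1 stood at 0.638 times PBS (0.630 to 0.647), MT-ND5 at 0.664 times, and MT-ND4L, the exception, at 1.19 times. All mitochondrial genes together took 8.38% of counts with A740003 (exact binomial 95% interval 8.37% to 8.39%), 9.39% with A438079 (9.37% to 9.40%) and 10.3% with PBS (10.3% to 10.4%). Progenitor and stem-like liver cancer genes had a median log2 ratio of -0.32 (percentile 0.03), with 12 of 16 below PBS and 1 at least 1.5-fold lower. AFP, the fetal albumin-like protein gene, stood at 0.713 times (0.699 to 0.727) and ALDH1A1 at 0.796 times, while PEG3 stood at 1.25 times.

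Wnt and beta-catenin targets had a median log2 ratio of -0.23 with A740003 (percentile 0.04; 2.76, inside the central 95%, with whole counts only), with 15 of 19 below PBS and 4 at least 1.5-fold lower. The transcription factor genes SP5 and TBX3 stood at 0.428 and 0.458 times, the Wnt feedback gene ZNRF3 at 0.485 times and TCF7 at 0.559 times, while LGR5 stood at 1.27 times. Acute phase and complement genes had a median of -0.17 (percentile 0.07; 3.54 with whole counts only), with 15 of 19 below PBS, 3 at least 1.5-fold lower and 1 at least 1.5-fold higher. C4A and C4B, near-identical complement genes that are uncertain for that reason, stood at 0.565 and 0.441 times, and at log2 ratios of -0.17 and -0.57 with the GC and length trend removed. SAA4 stood at 0.594 times, and HAMP, the gene of the iron hormone hepcidin, at 1.63 times (1.27 to 2.11). Of the 9 measured metallothionein and zinc transport genes, none reached 1.5-fold. The metallothionein genes MT1E, MT1X, MT1G, MT1F and MT2A stood at 1.45, 1.39, 1.39, 1.31 and 1.27 times PBS, with counting intervals above 1, and the zinc exporter gene SLC30A1 at 0.753 times. That list lay at percentile 99.9, at percentile 97.6 with the GC and length trend removed, and at percentile 96.4, inside the central 95%, with FPKM.

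Hepatocyte transcription factors had a median of -0.20 with A740003 (percentile 2.30), and of -0.11 (percentile 5.38, inside the central 95%) with the GC and length trend removed. RXRA and FOXA1 stood at 0.305 and 0.476 times PBS, and NR0B2, a repressor of bile acid synthesis genes, at 1.73 times (1.55 to 1.94). YAP and TEAD targets had a median of -0.22 (percentile 2.44), with CCN2 at 0.585 times and AJUBA at 0.565 times, and a median of -0.02 with the GC and length trend removed. PXR and CAR targets had a median of -0.16 (percentile 1.73; 8.12 with that trend removed and 23.0 with FPKM) but a mean of 0.02, and UGT1A1 and UGT1A3 were the 2 members at least 1.5-fold higher. All 6 measured cholangiocyte markers lay below PBS in both antagonist libraries, with medians of -0.32 and -0.26, and of -0.23 and -0.13 (percentiles 3.44 and 4.95, inside the central 95%) with that trend removed. KRT19, a keratin of bile duct cells that liver cancer lines also express, stood at 0.801 times with A740003 and 0.910 times with A438079.

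The second comparison asked how cells given A438079 differed from cells given PBS. Genes of cholesterol synthesis were lower together: 23 of the 24 measured members of the cholesterol synthesis and SREBP2 list lay below PBS, the median log2 ratio was -0.49, and the median was below all 10000 random lists. LSS, the lanosterol synthase gene, stood at 0.401 times PBS (95% counting interval 0.354 to 0.453; 363 against 908 counts). MVD, which acts earlier in the same synthesis, stood at 0.420 times (0.358 to 0.490). FASN stood at 0.178 times (0.150 to 0.210). Among all genes compared, 104 were at least 2-fold higher and 459 at least 2-fold lower in the A438079 library. At a mean of at least 5 CPM, 12 were higher and 133 lower. Over all genes, unchanged libraries simulated at an assumed coefficient of variation of 0.2 gave 181 higher and 172 lower genes here. At 0.1 they gave 22.7 and 19.5.

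Of the 24 cholesterol genes, 8 were at least 1.5-fold lower with A438079 and none was higher. DHCR7 stood at 0.574 times PBS (0.528 to 0.624), FDFT1, the squalene synthase gene, at 0.607 times (0.585 to 0.628), and IDI1 at 0.666 times. HMGCS1, an early enzyme gene of the pathway, stood at 0.709 times (0.683 to 0.735). SREBF2, which encodes the transcription factor of this pathway, stood at 0.470 times with A438079 and at 0.425 times with A740003. PMVK, the exception, had 219 counts in both libraries. These single ratios are given before the GC and length trend was removed. The list's median was -0.53 with that trend removed. With A740003 the same list had a median of -0.04 (percentile 9.75), with 14 of 24 below PBS. Of these, 3 were at least 1.5-fold lower, LSS and SREBF2 among them, so LSS was low with both antagonists.

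**Figure D1:**
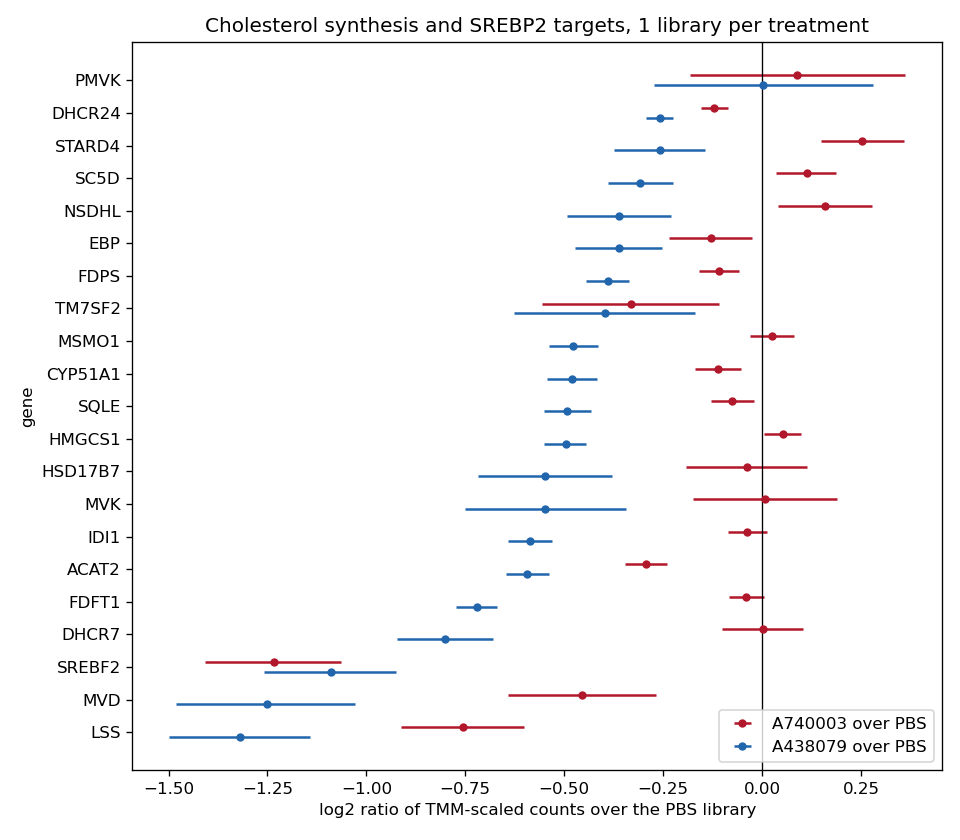
Log2 ratio of scaled counts over the PBS library (x axis) for 21 of the 24 measured cholesterol synthesis and SREBP2 genes (y axis) with A740003 (red) and A438079 (blue), 1 library each. Bars are 95% counting intervals; with A438079, 20 of the 21 points lie below 0.

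Apart from FASN and a readthrough gene described below, the lowest genes with A438079 included AGRN, a basement membrane proteoglycan gene, at 0.228 times PBS and LRP1, a large endocytic receptor gene, at 0.285 times. PRRC2A, HCFC1, SOGA1 and TTYH3 stood at 0.292, 0.290, 0.315 and 0.318 times, and IGF2 at 0.353 times (0.335 to 0.371). The median GC content of the lower genes was 60.9% and their median length 4018 nt. With the GC and length trend removed, 98 genes were at least 2-fold higher and 198 lower, so that lower genes made up 66.9% of those past the threshold instead of 81.5%. Only 5 genes met the rule for the highest, and all 5 had fractional counts: SULT1A4, FAM156A, RN7SL1, RPL36A-HNRNPH2 and ZNF625-ZNF20. SULT1A4 stood at 40.1 times PBS, but its counts summed with those of its near-identical copy SULT1A3 stood at 0.988 times (0.941 to 1.04). BLOC1S5-TXNDC5, a readthrough, had 0 counts with A438079, 65 with PBS and 237 with A740003. Its sum with TXNDC5 stood at 0.991 times PBS (0.970 to 1.01) with A438079. That sum was 16601 against 16789 counts, too many for the readthrough to move it.

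Of the 39 lists, 13 had a median below the central 95% of random lists in the A438079 library over PBS and none had a median above it. With the GC and length trend removed, 7 lay below and none above. Fatty acid and triglyceride synthesis genes had a median of -0.18 (percentile 0.01; 5.58, inside the central 95%, with whole counts only), with 16 of 22 below PBS and 6 at least 1.5-fold lower. The desaturase gene FADS2 stood at 0.541 times, the lipogenic transcription factor gene MLXIPL at 0.566 times and PNPLA3 at 0.614 times, and their log2 ratios were -0.39, -0.20 and -0.66 with the GC and length trend removed. With A740003 that list had a median of 0.00 and a mean of -0.30, with 6 of 22 at least 1.5-fold lower. NF-kB targets and chemokines had a median of -0.23 with A438079 (percentile 0.32), with 4 of 16 at least 1.5-fold lower. Among them NFKB2 stood at 0.570 times and CX3CL1 at 0.586 times (log2 ratios of -0.14 and -0.50 with the GC and length trend removed), and CCL20 at 0.756 times (0.728 to 0.786).

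NRF2 targets had a median of -0.06 with A438079 (percentile 0.11), with 2 of 26 at least 1.5-fold lower. AKR1C1, an aldo-keto reductase gene with close paralogs, stood at 0.666 times PBS with A438079 and 0.567 times with A740003. The median of the integrated stress response list was -0.14 (percentile 0.09) and 0.03 with the GC and length trend removed. Its members SLC7A5 and TRIB3 stood at 0.515 and 0.466 times, and at log2 ratios of -0.36 and -0.77 with that trend removed. Glycolysis and hypoxia genes had a median of -0.12, below all 10000 random lists, and -0.02 (percentile 5.69) with that trend removed. PFKL and PFKFB3 stood at 0.684 and 0.663 times, and at log2 ratios of -0.016 and -0.37 with that trend removed. Mitochondrial mRNAs had a median of -0.08 (percentile 0.265), with 7 of 13 below PBS and none past 1.5-fold, but lay at percentile 10.5 with that trend removed, and the median was above 0 with whole counts only (0.0406). Cytosolic ribosomal protein genes had a median of -0.02 (percentile 0.08), with none of 40 past 1.5-fold, but lay at percentile 36.9 among random lists matched also on length, and the median was above 0 under upper quartile scaling (0.0301) and with whole counts only (0.0638). Wnt targets had a median of -0.14 (percentile 0.295; 4.29 with the trend removed and 15.5 with FPKM) and progenitor genes -0.14 (percentile 0.62; 1.21 with the trend removed and 4.19 with FPKM). Acute phase genes had a median of -0.04 (percentile 2.11; 12.5 with the trend removed), which was above 0 under upper quartile scaling (0.0054) and with whole counts only (0.0576).

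The third comparison set the antagonists against each other at the same dose and time. The cholesterol genes separated them: 23 of 24 were higher with A740003 than with A438079, the median log2 ratio was 0.49, and 4 were at least 1.5-fold higher. The ratio of A740003 over A438079 was 1.75 (95% counting interval 1.61 to 1.90) for DHCR7, 1.74 (1.48 to 2.05) for MVD and 1.60 (1.55 to 1.66) for FDFT1. SREBF2 did not separate them, at 0.904 (0.788 to 1.04). IGF2 was lower with A740003 than with A438079, at 0.483 (0.447 to 0.521; log2 ratio -1.05, and -0.84 with the GC and length trend removed), and the UGT1A rows together were higher, at 1.62 (1.52 to 1.72). Among all genes compared, 120 were at least 2-fold higher and 142 at least 2-fold lower with A740003. At a mean of at least 5 CPM, 5 were higher and 22 lower. This comparison was not simulated. Over PBS, unchanged libraries gave 172 to 181 genes each way at an assumed coefficient of variation of 0.2, and 19.5 to 22.7 at 0.1. Simulated log2 ratios over PBS had standard deviations of 0.449 and 0.450 at 0.2, and of 0.270 and 0.271 at 0.1. The observed value between the antagonists was 0.421 over all genes compared and 0.191 at a mean of at least 10 CPM, any effects included. A variation of 0.2 in every gene would thus give a wider spread than these libraries show. Their real variation was not measured, so whether counts of this size need an effect stays open.

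FOXQ1, SKI and SBF1 stood at 0.418, 0.428 and 0.422 with A740003 over A438079, and at log2 ratios of -1.28, -1.01 and -0.86 with the GC and length trend removed. GSTA2, a glutathione transferase gene with close paralogs, stood at 0.489 (0.426 to 0.561), RGPD6 at 0.470, SMIM11 at 0.465 and BZW1P2 at 0.186, all with fractional counts. Only BLOC1S5-TXNDC5, FAM156B and CMC4 met the rule for the highest, and CMC4 stood at 2.43 (1.82 to 3.27). FAM156A and FAM156B went opposite ways at 0.462 and 2.33, and summed to 1.17 (1.01 to 1.35). All 13 mitochondrial mRNAs had ratios below 1, none of them at least 1.5-fold lower, with a median of -0.22. Acute phase genes had a median of -0.16, and both medians were below all 10000 random lists. FGB, a fibrinogen chain gene, stood at 0.665 (0.632 to 0.699). Metallothionein and zinc transport genes had a median of 0.27, above all 10000 random lists, with MT1F at 1.57 (1.26 to 1.97).

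Fatty acid synthesis genes had a median of 0.11 with A740003 over A438079 (percentile 99.9), autophagy and lysosome genes 0.09 (percentile 99.6), NRF2 targets 0.06 (percentile 99.49), integrated stress response genes 0.09 (percentile 99.2), NF-kB targets 0.14 (percentile 99.2), glycolysis genes 0.06 (percentile 98.4) and ribosomal protein genes 0.02 (percentile 98.2). With whole counts only, fatty acid synthesis (percentile 69.2), integrated stress response (94.9) and glycolysis (88.6) lay inside the central 95%. NF-kB targets (97.2) and ribosomal protein genes (84.5, with a median of -0.0024) did so with the GC and length trend removed. FTL, the ferritin light chain gene, which has pseudogenes that may share its reads, stood at 1.38 (1.37 to 1.39). YAP and TEAD targets had a median of -0.18 (percentile 0.33), progenitor genes -0.12 (percentile 1.06) and Wnt targets -0.09 (percentile 2.06), but YAP and TEAD targets lay at percentile 4.89 and progenitor genes at 2.5 with FPKM, and Wnt targets at 6.27 with whole counts only. DKK1, a secreted Wnt inhibitor gene, stood at 0.720 (0.711 to 0.729), and TCF7 at 0.589.

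The antagonist libraries also shared genes relative to PBS. Lower in both were 301 genes, of 670 with A740003 and 459 with A438079, and higher in both were 57. Lists of these sizes drawn independently would share 25.1 lower and 1.20 higher genes. Unchanged libraries simulated against the shared PBS library shared 0.41, 1.29 and 17.4 lower genes and 2.41, 5.49 and 45.4 higher genes. The assumed coefficients of variation were 0, 0.1 and 0.2. The simulated lists of lower genes were shorter, with 8.26, 19.7 and 175 genes for A740003 and 8.45, 19.5 and 172 for A438079. The simulations also held no trend with GC content and length. Of the genes higher in both, only FAM156A, RN7SL1 and RPL36A-HNRNPH2 met the naming rule, with a symbol and a mean of at least 5 CPM. All of them had fractional counts, and FAM156A summed with FAM156B stood at 1.23 and 1.06 times PBS with A740003 and A438079. Genes lowest in both were FASN, AGRN, LRP1, PRRC2A, IGF2, TTYH3, HCFC1, SOGA1, CLUH and POLR2A. FASN and SOGA1 stayed at least 2-fold lower in both with the GC and length trend removed. AGRN was at a log2 ratio of -0.72 with A740003, and LRP1, PRRC2A, IGF2, TTYH3, HCFC1 and CLUH were between -0.89 and -0.80 with A438079. POLR2A hardly moved, from -1.76 to -1.77 with A740003 and from -1.56 to -1.50 with A438079. The length used for POLR2A was 2083 nt, and its value with the trend removed holds only if that length does. CLUH, whose product binds mRNAs of mitochondrial proteins, stood at 0.192 times PBS (0.143 to 0.254) with A740003 and 0.321 times (0.252 to 0.405) with A438079. POLR2A, the largest subunit gene of RNA polymerase II, stood at 0.294 and 0.339 times. AGRN did not differ between the antagonist libraries within counting error, at 1.01 (0.678 to 1.51).

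**Figure D2:**
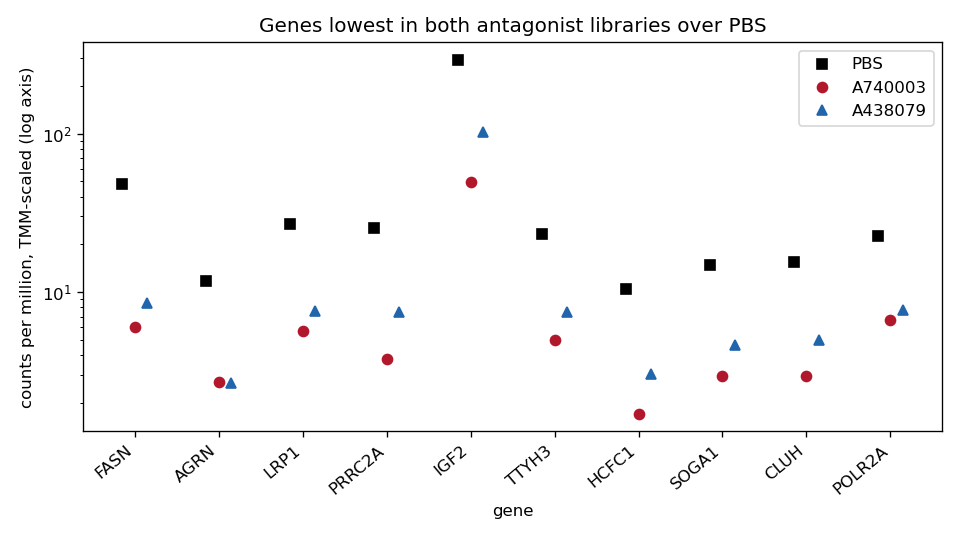
Scaled counts (CPM; y axis, log scale) in the PBS, A740003 and A438079 libraries for the 10 genes (x axis) lowest in both antagonist libraries, 1 library each. Every gene lies below its PBS value in both antagonist libraries (IGF2 at 49.6 and 103 against 291 CPM), without removal of the GC and length trend.

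Across genes, the log2 ratios of both antagonists over PBS had a Pearson correlation of 0.690 and a Spearman correlation of 0.733; genes are not independent replicates. Unchanged libraries simulated against the shared PBS library gave Pearson values of 0.5009, 0.5008 and 0.4997 at the same coefficients of variation. The covariance was 0.194, against simulated values of 0.0156, 0.0367 and 0.101. With 1 PBS library the control could not be split, so part of the excess may come from it. The 327 genes with a GC content of at least 55.9% and a length of at least 5051 nt had median log2 ratios of -1.09 with A740003 and -0.81 with A438079, and the 1172 equally long genes with the lowest GC content (up to 41.8%) had medians of 0.20 and 0.17.

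**Figure D3:**
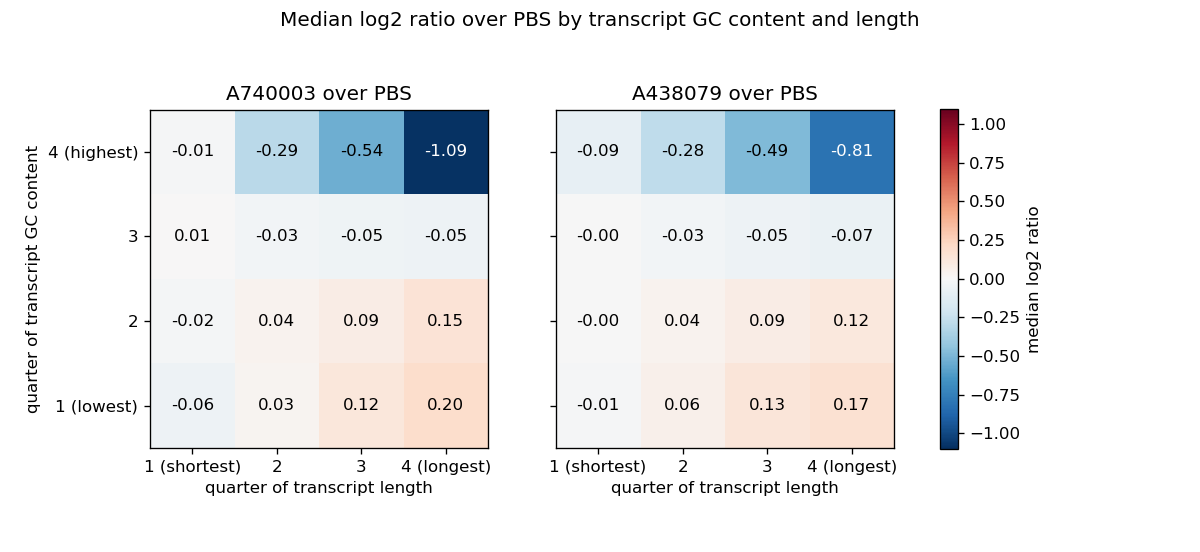
Median log2 ratio over PBS (colour and printed value) of genes grouped by transcript length (x axis) and transcript GC content (y axis), 4 groups of each, for A740003 (left) and A438079 (right). The longest and most GC-rich genes have the lowest medians, -1.09 and -0.81.

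Of the 39 lists, 21 had medians within the central 95% of random lists in all 3 comparisons. Among them were the inflammasome and IL-1 family, with 12 of 22 genes measured and medians of -0.12 with A740003 and -0.17 with A438079. CASP4 stood at 0.806 and 0.779 times PBS and TXNIP at 0.916 and 1.18 times. The G2/M list had medians of 0.05 in both, apoptosis regulators 0.07 and 0.02, p53 targets -0.07 and -0.02, secreted hepatocyte proteins -0.01 and 0.04, and nuclear oxidative phosphorylation genes 0.04 and 0.02. Single members of these lists stood apart, such as ITPR3, an endoplasmic reticulum calcium channel gene, at 0.379 and 0.510 times (log2 ratios of -0.30 and -0.14 with the GC and length trend removed), IRS1, an insulin signalling adaptor gene, at 0.384 and 0.461 times, and APOB, the apolipoprotein of liver lipoproteins, at 1.39 and 1.32 times. Of markers of other cell types, 1 of 15 fibroblast genes (ACTA2), 1 of 11 endothelial genes (ESAM) and 4 of 19 leukocyte genes were measured. ACTA2 had 381, 418 and 399 counts and ESAM 13, 27 and 34 counts with A740003, A438079 and PBS. LYZ, the lysozyme gene, stood at 0.919 and 0.913 times PBS.

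**Figure D4:**
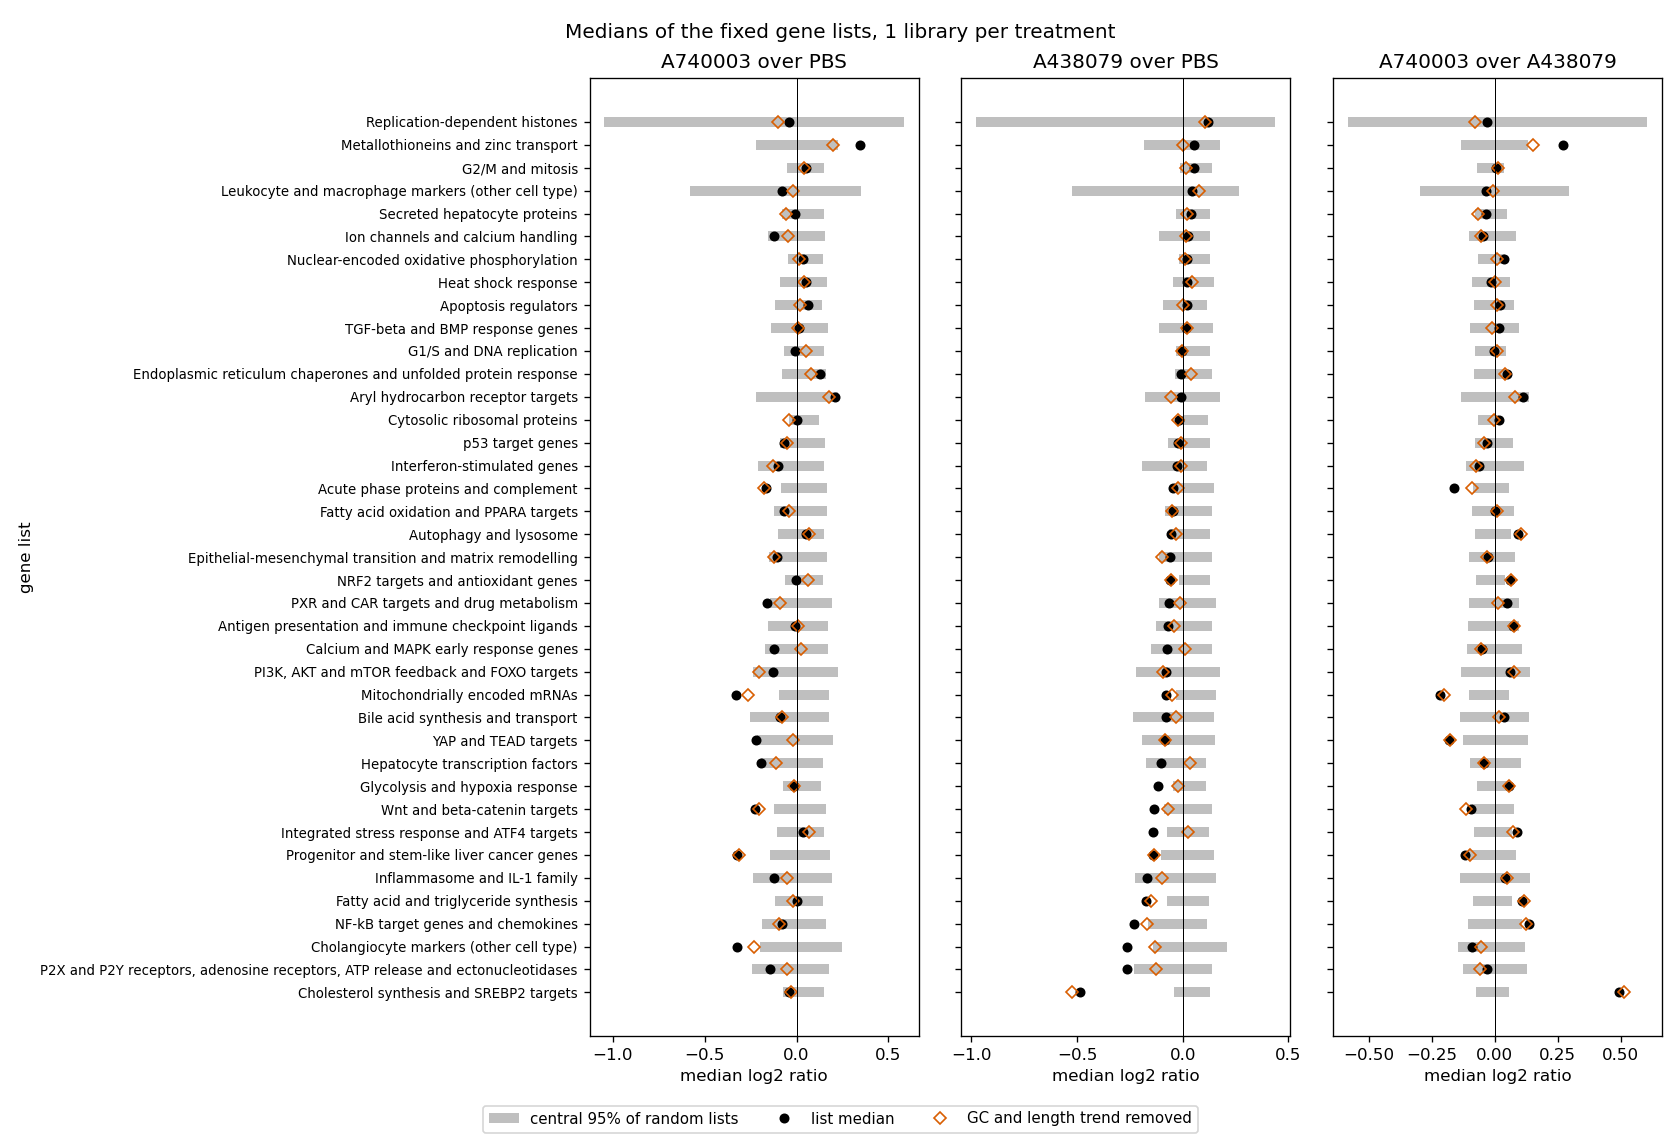
Median log2 ratio (x axis) of each fixed gene list (y axis) in the 3 comparisons: filled points are list medians, grey bars the central 95% of random lists matched on expression for those medians, and open diamonds the medians with the GC and length trend removed, to which the bars do not apply. The cholesterol list lies at -0.49 with A438079 over PBS and at 0.49 with A740003 over A438079.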

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

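The alternatives with the GC and length trend removed, with whole counts only, with random lists matched also on GC content and with counts not rounded were chosen after the data were seen; the others were fixed before. Over the 3 other scalings and the unrounded counts, genes at least 2-fold lower outnumbered those higher in both antagonist libraries over PBS, and the alternatives that moved a count by less than 1.5 times gave 602 to 670 lower and 125 to 176 higher genes with A740003, 397 to 515 and 98 to 125 with A438079, and 97 to 174 and 101 to 123 for A740003 over A438079.

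In the order higher and lower with A740003 over PBS, higher and lower with A438079 over PBS, and higher and lower with A740003 over A438079, the counts were 516, 1151, 416, 938, 498 and 428 with no filter on low values. They were 16, 279, 12, 133, 5 and 22 at a mean of at least 5 CPM, and 5, 151, 6, 48, 2 and 12 at 10 CPM. Of the 12270 genes, 9589 and 8196 were then compared, so these counts fell by more than the number of genes did. Most genes past the threshold thus had a mean below 5 CPM. They were 385, 1313, 200.0, 1158, 300.0 and 345 at 1.5-fold and 20, 112, 25, 34, 21 and 27 at 4-fold. With the whole interval beyond 2-fold they were 30, 262, 33, 111, 23 and 29, with FPKM and a pseudocount of 1 they were 52, 242, 42, 138, 48 and 44, and with whole counts only they were 36, 408, 20, 277, 38 and 59. The FPKM pseudocount of 1 shrinks ratios of low genes. With FPKM and a pseudocount of 0.1, 194 genes were higher with A740003 over A438079. Protein-coding genes alone gave 72, 49 and 73 higher genes in the 3 comparisons. With the GC and length trend removed, 284 and 198 genes were lower with A740003 and A438079 over PBS.

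The correlation between the antagonists was 0.7595 at 5 CPM, 0.817 at 10 CPM, 0.734 with a pseudocount of 5 counts, 0.733 as Spearman and 0.612 with the GC and length trend removed.

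The cholesterol list kept its direction and its place outside the random lists with A438079 over PBS and between the antagonists under every alternative run. No list changed its call under total counts or DESeq2 size factors. For the other lists, the cause of the differences below was not tested.

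With the GC and length trend removed, medians moved inside the central 95% of random lists for these. With A438079 over PBS they were acute phase -0.0234, cholangiocyte -0.13, glycolysis -0.0223, mitochondrial mRNAs -0.0519, purinergic -0.13 and Wnt -0.0706, and with A740003 cholangiocyte -0.23, hepatocyte transcription factors -0.11, PXR and CAR -0.0884 and YAP -0.021. Between the antagonists NF-kB did (0.13). The sign reversed for integrated stress response with A438079 (0.027) and for ribosomal proteins between the antagonists (-0.0024), and matrix remodelling with A438079 moved outside (-0.0976).

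With whole counts only, those that moved inside with A438079 were cholangiocyte -0.20, fatty acid synthesis -0.11, glycolysis -0.0887, progenitor -0.14 and purinergic -0.12. With A740003 they were acute phase -0.20, hepatocyte transcription factors -0.23, PXR and CAR -0.25 and Wnt -0.18, and between the antagonists fatty acid synthesis 0.0118, glycolysis 0.0583, integrated stress response 0.0886 and Wnt -0.0905. The sign reversed with A438079 for acute phase (0.0576), mitochondrial mRNAs (0.0406) and ribosomal proteins (0.0638), as it did under upper quartile scaling for acute phase (0.0054) and ribosomal proteins (0.0301). With A740003 p53 targets (-0.27) and aryl hydrocarbon receptor targets (0.58) moved outside, as did p53 targets (-0.16) and antigen presentation (0.28) between the antagonists. The median moved, without a change of place inside or outside, for autophagy between the antagonists (0.19), for ribosomal proteins with A740003 (0.16) and between the antagonists (0.12), for aryl hydrocarbon receptor targets with A438079 (0.24) and for the PI3K list between the antagonists (-0.0872); in the last 2 the sign turned from small medians of -0.009 and 0.059.

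With FPKM, those that moved inside with A438079 were glycolysis -0.0821, progenitor -0.13, purinergic -0.0977 and Wnt -0.0794. With A740003 they were hepatocyte transcription factors -0.16, metallothioneins 0.20, PXR and CAR -0.0521 and YAP -0.17, and between the antagonists glycolysis 0.0829, integrated stress response 0.0937, progenitor -0.083 (percentile 2.5) and YAP -0.0919. Those that moved outside with A740003 were fatty acid oxidation -0.15, NF-kB -0.24 and p53 targets -0.14, and between the antagonists aryl hydrocarbon receptor targets 0.17, matrix remodelling -0.14 and nuclear oxidative phosphorylation 0.0895. The median moved, on the same terms, with A438079 for mitochondrial mRNAs (-0.19), NRF2 (-0.15), nuclear oxidative phosphorylation (-0.0562), ribosomal proteins (-0.12) and secreted hepatocyte proteins (-0.0713), with a turn of sign for nuclear oxidative phosphorylation (from 0.021) and secreted hepatocyte proteins (from 0.038), and for ribosomal proteins between the antagonists (0.0685).

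At 5 CPM purinergic with A438079 (-0.002) and PXR and CAR (-0.081) and YAP (-0.11) with A740003 moved inside, and chaperones (0.0473) and ion channels (-0.0984) between the antagonists moved outside. Against random lists matched also on length, ribosomal proteins with A438079 (-0.0194) and PXR and CAR (-0.16) and YAP (-0.11) with A740003 moved inside. Matched also on GC content, acute phase (-0.0441), integrated stress response (-0.14), mitochondrial mRNAs (-0.0797), progenitor (-0.14), purinergic (-0.27) and ribosomal proteins (-0.0194) with A438079 moved inside, as did glycolysis (0.0571), ribosomal proteins (0.0194) and Wnt (-0.0935) between the antagonists, and aryl hydrocarbon receptor targets (0.21) and matrix remodelling (-0.11) with A740003 moved outside.

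Of the named genes' log2 ratios that were at least 1.5-fold with a counting interval that excluded 1, 5 reversed, and the cause was not tested. With FPKM, A740003 over A438079 was 0.0196 for PRRC2A, 0.0539 for SCRIB, 0.34 for PIEZO1 and 0.10 for SOGA1. With the GC and length trend removed, A740003 over PBS was 0.0368 for SLC4A2. In that setting 20 of 81 such ratios with A740003 over PBS, 30 of 66 with A438079 over PBS and 5 of 31 between the antagonists were no longer past 1.5-fold. Of the smaller ratios, 5, 6 and 3 changed sign, ADORA2A with A740003 and P2RX4, CMC4 and TCF7 with A438079 among them. None reversed under total counts or DESeq2 size factors. Others left the counting interval of the ratio: 148 with FPKM and 143 with the GC and length trend removed, against 367 and 369 that stayed within it, and 15 under total counts.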

Other observations

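All patterns below were picked after the data were seen; the test of cholesterol genes by whole counts and the 3 tests of summed loci were then written before their own values were seen, and the other tests and the pathway search were chosen after the results were seen.

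Pathways in the deposited KEGG annotation were searched without a fixed hypothesis, as a description of these libraries: 141 pathways of 15 to 150 measured genes, each against 2000 random lists, with the GC and length trend removed. Outside the central 95% lay 13 with A740003 over PBS, 12 with A438079 over PBS and 11 with A740003 over A438079. If genes varied independently, 7.05 would lie outside, but members of a pathway can vary together. With both antagonists, and both before and after the trend was removed, only the ribosome and primary bile acid biosynthesis lay outside. Ribosome genes had medians of -0.04 and -0.01 before and percentiles of 0.25 and 0.95 after, while the fixed list of cytosolic ribosomal proteins lay inside with A740003 (percentiles 18.6 and 10.9 before and after). Primary bile acid biosynthesis was low, at median log2 ratios of -0.24 and -0.17 before the trend was removed and percentiles of 0.45 and 0.70 after it, while the fixed bile acid synthesis and transport list lay inside the random lists with both (percentiles 25.2 and 27.1; 15.95 and 23.2 with the trend removed). Among its annotated members AKR1C1 had 27098, 31007 and 46622 counts and AKR1C2 32136, 36797 and 43131 counts with A740003, A438079 and PBS, while SLC27A5, a bile acid ligase gene, had 241, 158 and 131 counts. The annotation also places CCDC85C in this pathway, so the deposited assignment is loose. For 5 other pathways the medians lay outside the random lists with both antagonists only once the trend was removed. Motor protein genes lay at percentiles 93.7 and 85.5 before and 99.8 and 99.55 after, and arachidonic acid metabolism genes at 3.9 and 1.1 before and 2.3 and 1.4 after. Ferroptosis genes had medians of -0.003 (percentile 19.1) with A740003 and -0.019 (percentile 1.93) with A438079 before, and -0.10 and -0.07 after. Phagosome genes lay at percentiles 99.2 and 83.1 before, with medians of 0.09 and 0.07 after. Oxidative phosphorylation genes lay at percentiles 94.2 and 55.1 before, with medians of 0.06 and 0.04 after, while the fixed list of nuclear oxidative phosphorylation genes stayed inside the random lists after it (percentiles 68.4 and 47.0).

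Single respiratory chain genes stood apart from PBS, more in the A740003 library than in the A438079 library. With A740003, COX8A had 701 counts against 348 with PBS, a log2 ratio of 0.97, NDUFA7 387 against 230, NDUFA2 970 against 635 and COX6A1 2494 against 1667, while UQCRFS1 had 484 against 787. With A438079 these genes had 499, 290, 819, 1931 and 640 counts, each on the same side of PBS. The higher ones have short transcripts, of 507, 601, 804 and 572 nt in that order, against 3475 nt for UQCRFS1. With the GC and length trend removed, their log2 ratios with A740003 were 0.85, 0.58, 0.51 and 0.46, and that of UQCRFS1 was -0.79. NDUFA7, NDUFA2 and UQCRFS1 had fractional counts. TFRC, the transferrin receptor gene, had 7187, 7361 and 5013 counts with A740003, A438079 and PBS, and SCARB1, a lipoprotein receptor gene, had 579, 636 and 1248. These genes were chosen after their values were seen.

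The excess of lower genes in both antagonist libraries may come largely from a difference in how library preparation kept long, GC-rich transcripts. A ratio cannot say whether the antagonist libraries lost them or the shared PBS library held more. Rank correlations of log2 ratio with GC content were -0.375 with A740003 and -0.464 with A438079 over PBS. For A740003 over A438079 the value was -0.019, although the longest and most GC-rich genes had a median of -0.27 there. The longest and most GC-rich genes as a whole, not only those past 2-fold, lay low in both, with the smaller drop at a median log2 ratio of -0.81. Degraded RNA that loses long transcripts of any composition is argued against by the longest, least GC-rich genes, whose lower median was 0.171, and the choice of scaling by at least 3.786 lower genes per higher gene under 3 other scalings. Whether reads were missing from part of each transcript stayed open, since the transcript length implied by count and FPKM had a median log2 ratio of -0.019 in the library with the smaller drop. With the trend removed 87 genes were lower in both, but both comparisons share the PBS library and no shared-control value was simulated for them. An effect of the compounds or their solvent on long, GC-rich genes stays open, as treatment and library cannot be separated with 1 library each.

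The median of the cholesterol genes was low with A438079 and near 0 with A740003 at the same dose and time. Before the GC and length trend was removed, however, 3 of 24 members were at least 1.5-fold lower with A740003, LSS and SREBF2 among them. The GC and length trend is argued against as the cause, since the list's median was -0.525 with the trend removed, and so are reads shared with paralogs or pseudogenes, since the 13 members with whole counts had a median of -0.477. Variation between single cultures, such as density or medium sterol, cannot be told apart from the compound with 1 library per treatment. A hypothesis for a repeat with replicates is that A438079 may lower SREBP2 target genes in HepG2 cells more broadly than A740003 does, through a route that need not involve P2RX7, which had 2 counts per library.

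The extreme ratios of SULT1A4 and FAM156A likely reflect how reads were divided between copies. SULT1A4 stood at 40.1 times PBS with A438079, but its sum with SULT1A3 stood at 0.9879 times (0.941 to 1.04). BLOC1S5-TXNDC5 had 237 counts with A740003 and 0 with A438079, and its sum with TXNDC5 gave a ratio of 0.9658 (0.945 to 0.987). The sums were 16470 and 16601 counts, so they would be nearly equal whatever the readthrough did. They cannot show how its reads were divided. FAM156A stood at 8.36 times PBS with A438079, but its sum with FAM156B stood at 1.0564 times (0.906 to 1.23). No biological explanation was tested for these loci.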
